A study of Mus musculus with 9 samples.

How the data were processed

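RNA from interscapular brown fat was sequenced in 9 samples, 5 with the control guide and 4 with the Ucp1 guide. The submitters' processing notes name FastQC, STAR and DESeq2 and the genome build GRCm39, without versions or the role of each. The annotation release, the strand setting and the counting mode are not given in the sources used here. The deposited table holds whole-number counts per Ensembl gene identifier.

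The name of each of the 9 value columns, and the number within it, was searched for in every text of the sample labels and the series description, and 0 matched. All 9 columns were left out of every step, since a column was to be given to a sample only by its name. The planned tests between the guides, with their gene lists and alternatives, were fixed before the data were examined and were not run.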

Results

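The series concerns the effect of targeting Ucp1 with a guide RNA in the brown fat of adult mice. Ucp1 encodes the uncoupling protein of the inner mitochondrial membrane through which brown adipocytes release energy as heat. Cas9-expressing C57BL/6J mice received an AAV8 vector (an adeno-associated virus) in the interscapular brown fat, carrying a guide RNA against Ucp1 or a control guide RNA. The animals were then housed at 22 °C for 14 days before RNA sequencing of the tissue. The labels give 9 samples, of which 5 received the control guide and 4 the Ucp1 guide.

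The design implies a comparison of gene expression between the Ucp1 guide and the control guide. The Ucp1 transcript itself was to be the first check of the labels, although cutting by the guide need not lower it. The comparison between the guides was not made. The gene count table has 9 value columns, each named by a number followed by the abbreviation BAT, and 0 of these names or numbers occur in the sample labels or the series text. Neither the order of the columns nor their values was used to place them in a group. No expression value, fold change or test is therefore reported, for Ucp1 or for any other gene.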

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

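The count of columns whose name or number occurs in a label was 0 of 9. It was also 0 under both other matching rules, which were not planned and were chosen after the result of the first search was known. One compared names without spaces and punctuation, and the other accepted the number inside any longer number or accession. No paired analysis was possible because the columns of the count table carry no replicate number or group. The sample titles also do not state that equal replicate numbers under the control guide and the Ucp1 guide form pairs. The groups differ in size, with 5 control and 4 Ucp1 samples. No normalisation, filter, test or left-out replicate was tried on the counts, since all 9 columns were left out.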
